A study of Homo sapiens with 8 samples.

How the data were processed

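Human embryonic stem cells of the H1 line were carried by directed differentiation toward pharyngeal foregut endoderm, and single cells were profiled with Drop-seq at 4 stages. The stages are undifferentiated stem cells (hESC, 3 libraries), definitive endoderm (hDE, 2 libraries), anterior foregut endoderm (hAFE, 2 libraries) and pharyngeal foregut endoderm (hPFE, 1 library). Per the labels' protocols, cells were lifted with TrypLE, sorted as single cells, captured in droplets with barcoded oligo-dT beads, reverse transcribed, tagmented with Nextera XT and sequenced paired-end on a NextSeq. The labels name no gate for the sort, and culture days and growth factors are not given in the sources used here. Stage and replicate number come from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

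The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, 1 matrix per library, not normalised, per the labels and the values themselves. Per the submitters' processing notes, the tools named are STAR 2.7.10, Picard 2.26.10 and Scanpy 1.9.1, with the genome build hg38. The matrices count exon-tagged molecules. The gene annotation, the strand setting and the rule by which the authors chose which barcodes to deposit are not given in the sources used here. Antisense and overlapping genes (GATA6-AS1, LHX1-DT) and near-identical paralogs (PRSS1 and PRSS2) are therefore uncertain. The union of the matrices holds 29846 gene names, of which 29357 matched a name in the reference table. A gene missing from a library's matrix was counted as 0 there. Gene locations are GENCODE v29 gene models on GRCh38, the build that hg38 names.

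A barcode was kept as a cell with at least 500 genes detected and at most 20% of its UMIs from mitochondrially encoded genes, which left 17870 of 102060 deposited barcodes. The mitochondrial limit removed 1 further barcode. UMIs of kept cells were summed per library, since cells are not replicates. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM scaling, genes chosen by filterByExpr, and all 8 libraries in a model with stage as its only term. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The model tested 16729 genes with 4 residual degrees of freedom, and its common biological coefficient of variation was 0.223. Since hPFE has 1 library, its spread was assumed to be that of the other stages, and no replicate checks it. Levels are counts divided by TMM-scaled library totals (CPM). The standard error (SE) of a log2 fold change is its absolute value divided by the square root of the F statistic. For hPFE, an exact 95% Poisson interval of the count stands in place of an SD. It covers counting error only. Where a stage had 0 UMIs of a gene, the fold is given as a bound against 3 counts over that stage. With 1 to 3 UMIs, the ratio of CPM is given with its 95% counting interval.

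The genes named were fixed by rule. Among changed genes with at least 50 CPM in the higher stage and every library of one stage above every library of the other, the 10 largest rises and 10 largest falls of each comparison were taken, leaving out clone-based names, Y-linked genes and XIST. Up to 4 members per gene list with the smallest adjusted p, and the stage markers, were added. A named gene outside this rule is said to be so. Some genes that the rule takes are not reported here. The gene lists, 25 in number, cover pluripotency, primitive streak, definitive endoderm, anterior foregut, pharyngeal endoderm, the 3-prime HOX genes, epithelial genes, posterior endoderm and liver, mesoderm and mesenchyme, neural ectoderm, neural crest and surface ectoderm, amnion and trophoblast, endothelium and blood, targets of WNT, NODAL and activin, BMP, FGF and ERK, retinoic acid and hedgehog, the G2 and M phases, the S phase, glycolysis, cholesterol synthesis, stress and dissociation, and mitochondrially encoded genes. Each was tested in each comparison with camera (limma) on voom-weighted log2 CPM with a preset inter-gene correlation of 0.01, and p-values were adjusted over the 75 tests. The preset gave 28 calls. With the estimated inter-gene correlation 1 of them held, that of the definitive endoderm genes in hDE against hESC. In 11 of the 75 tests the median, the mean and the test of a list differed in sign, and none of these was a call. Of the listed genes, 32 are in more than 1 list. They include 10 of the 12 NODAL and activin targets, 9 of 14 primitive streak genes and 8 of 21 definitive endoderm genes. Calls of lists that share genes are not independent.

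The share of cells with a UMI of a stage marker was taken after thinning each cell to 800 UMIs and leaving out shallower cells, with an exact 95% binomial interval (Clopper-Pearson). A share of 0 allows up to 3 cells of the number used. Cells of all libraries were clustered together in scanpy 1.11.5 (Python 3.11.15) by the Leiden method at resolution 0.5, on 2000 variable genes, 30 principal components and 15 neighbours. A cluster was named only from at least 3 raised markers of a fixed list. Scrublet marked 67 of 17870 cells (0.375%) as doublets at an expected rate of 0.05, with 0.0675% in hESC replicate 3 and 3.76% in hAFE replicate 1 as the extremes. Whether the caller worked was not tested, so doublets are untreated. Genes with a peak or trough at 1 stage are those called in both successive comparisons in opposite directions. The count was set against the product of independent lists and against 20 simulated sets of unchanged libraries.

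The test was checked on simulated counts drawn from the real means and library sizes, with 50 genes changed at each fold. The changed genes were drawn only from those above a minimum mean CPM, so recovery of genes with low counts was not checked. At 2-, 3-, 4- and 8-fold it recovered 30, 84, 96 and 100% for hDE against hESC over 15792 genes, 32, 84, 100 and 100% for hAFE against hDE over 15800 genes, and 12, 52, 76 and 94% for hPFE against hAFE over 15775 genes. It made 11, 12 and 8 false calls. In each comparison, run over 16729 genes, the raised list was called. Among the other 74 list tests, 3, 1 and 3 were called. The simulated genes were drawn independently, so the check does not cover correlation between the genes of a list. The simulated hPFE library was given the spread fitted to the real libraries, which no hPFE replicate checks. Of 100 simulated 4-fold peaks, planted under the same minimum mean CPM, 99 were recovered at hDE over 15770 genes and 84 at hAFE over 15766 genes.

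Stages, comparisons, lists, markers, tests and most alternatives were chosen before the data were examined. The alternatives were DESeq2 1.42.0, RLE scaling, library totals without further scaling, no filter on low counts, cells with at least 1000 genes, all deposited barcodes, doublet calls left out, libraries thinned to the smallest total, a model of only the 2 stages compared, a replicate block, each replicate left out in turn, fry, and other cluster resolutions. Added after seeing the data were cells with at least 3000 UMIs, ribosomal protein and mitochondrial genes left out, and only genes whose longest coding transcript has at least 1500 nt.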

Results

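Gene expression was measured by 3-prime UMI counting in single H1 cells at 4 stages of differentiation toward pharyngeal foregut endoderm, the tissue that lines the embryonic throat. The 3 hESC libraries held 2332, 4034 and 4442 cells with 9347241, 9714668 and 9699478 UMIs. The 2 hDE libraries held 1017 and 1994 cells with 5428924 and 6492499 UMIs. The 2 hAFE libraries held 505 and 2201 cells with 2249648 and 6946607 UMIs, and the hPFE library held 1345 cells with 3761662 UMIs. Median UMIs per cell ran from 924 in hDE replicate 1 to 2853 in hAFE replicate 1. Replicates of every replicated stage differed by more than sampling noise (chi-square per degree of freedom from 11.1 to 23.4), so none was taken for a library deposited again, which does not tell whether they are separate cultures.

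The step from hESC to hDE addresses how stem cells become definitive endoderm, the germ layer of gut and airways. CER1, a secreted inhibitor of NODAL, BMP and WNT signals, stood at 9760 ± 157 CPM in hDE (SD, n = 2) against 0.110 ± 0.112 in hESC (n = 3), where it had 3 UMIs, a ratio of 90500 (counting interval 31000 to 439000). SOX17, a transcription factor that specifies endoderm, reached 318 ± 33.1 CPM and had 0 UMIs in hESC, at least 2930-fold higher. SOX2 fell from 1181 ± 196 to 8.30 ± 10.3 CPM (log2 fold change −7.19 ± 0.74 SE, adjusted p = 3.54e-05) and POU5F1 from 337 ± 75.3 to 5.97 ± 1.27 CPM (−5.82 ± 0.31, adjusted p = 3.66e-07). Both are core transcription factors of pluripotency. In all, 4633 of 16729 genes changed, 2211 higher and 2422 lower in hDE, and 6112 passed the adjusted p alone.

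Among the largest rises in hDE were NPPB, a natriuretic peptide gene, at 2426 ± 196 CPM against 1 UMI in hESC (ratio 67200, 12100 to 2650000), and GATA4, an endoderm and heart transcription factor, at least 1280-fold higher. DIO3, which inactivates thyroid hormone, was at least 2260-fold higher, the noncoding RNAs LINC02413 and LINC00479 at least 1390-fold and 1100-fold, and GATA6-AS1, antisense to GATA6, at least 1040-fold. PRSS2 and PRSS1, near-identical trypsinogen genes whose split is uncertain, were at least 3030-fold and 1860-fold higher (1710 and 1130 without hDE replicate 2). CER1 lies on chromosome 9 from 14719724 to 14722717 and SOX17 on chromosome 8 from 54457935 to 54460888. The largest falls in hDE included VSNL1, a neuronal calcium sensor, which had 0 UMIs and was at least 475-fold lower than its 133 ± 72.4 CPM in hESC. CNMD fell from 326 ± 8.0 to 0.491 ± 0.448 CPM (−9.38 ± 0.59), APELA, a peptide hormone of stem cells, from 168 ± 37.3 to 0.491 CPM (−8.43 ± 0.53), IDO1, a tryptophan-degrading enzyme, from 134 to 0.450 CPM (−8.11 ± 0.38), and PTPRZ1, a receptor phosphatase, from 353 ± 59.4 to 1.98 ± 0.336 CPM (−7.47 ± 0.30). Without hDE replicate 1 the log2 fold change of SOX2 was −10.11, that of CNMD −10.72 and that of APELA −9.76. Without hDE replicate 2 they were −6.24, −8.62 and −7.67, and that of IDO1 was −9.24.

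All 21 measured members of the definitive endoderm list rose in hDE, and all 21 passed when adjusted over the list alone (camera adjusted p = 2.54e-18; adjusted p = 0.0406 with an estimated correlation). Examples are CXCR4, the surface receptor used to isolate endoderm, from 1.95 ± 0.548 to 597 ± 145 CPM (8.25 ± 0.46, adjusted p = 5.26e-07), and GATA6 at 463 ± 18.3 CPM (ratio 4300, 1470 to 20900). FOXA2, a pioneer factor of endoderm, stood at 169.7 ± 8.27 against 0.260 ± 0.451 CPM (9.29 ± 0.54, adjusted p = 6.32e-07; 13.05 without hESC replicate 1, which held all 7 of its hESC UMIs, and 8.68 without hESC replicate 3). Of 11 primitive streak genes 10 rose, also when adjusted over the list alone (camera adjusted p = 5.49e-11; adjusted p = 0.177 with an estimated correlation), among them GSC (ratio 3180, 1090 to 15400) and FGF17 (5300, 1810 to 25700). Of 12 NODAL and activin targets 9 rose, 9 when adjusted over the list alone (camera adjusted p = 3.26e-09; adjusted p = 0.265 with an estimated correlation), with the feedback inhibitors LEFTY2 (10.97 ± 0.37) and LEFTY1 (9.31 ± 0.35) at 2284 ± 419 and 881 ± 185 CPM. Since 10 of these 12 genes are also in another list, this call is not separate evidence. Of 15 anterior foregut genes 9 rose and 1, SOX2, fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.253 with an estimated correlation). HHEX, a foregut transcription factor, rose from 2.83 ± 1.14 to 85.8 ± 37.1 CPM.

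Of 21 pluripotency genes 12 fell and 9 did not pass, 12 also when adjusted over the list alone (camera adjusted p = 3.45e-06; adjusted p = 0.172 with an estimated correlation). SFRP2, a secreted WNT modulator, fell by 7.01 on the log2 scale, USP44, a deubiquitinase, by 5.13 and POLR3G, an RNA polymerase III subunit, by 5.07. NANOG stood at 9.0 ± 0.128 in hDE against 16 ± 6.16 CPM in hESC (adjusted p = 0.118). Cell cycle genes fell in part. Of 18 G2 and M genes 6 fell, 6 when adjusted over the list alone (camera adjusted p = 3.68e-06; adjusted p = 0.314 with an estimated correlation), such as TOP2A, from 951 ± 89.1 to 316 ± 19.6 CPM. Of 17 S phase genes 5 fell, 5 when adjusted over the list alone (camera adjusted p = 0.000134; adjusted p = 0.464 with an estimated correlation), such as the replication helicase gene MCM3, from 649.9 ± 49.7 to 212 ± 20.8 CPM.

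Of 19 glycolysis genes 7 fell and 3 rose, 7 and 3 when adjusted over the list alone (camera adjusted p = 0.0199, lower; adjusted p = 0.620 with an estimated correlation). The glucose transporter gene SLC2A3 rose from 451 ± 68.5 to 3519 ± 95.9 CPM (2.96 ± 0.20), while the other glucose transporter gene SLC2A1 fell from 121 ± 15.3 to 19 ± 5.93 CPM. Without hESC replicate 3 the list's adjusted p was 0.0609, and with a replicate block it was 0.0646. Of 18 cholesterol synthesis genes 4 fell, 4 when adjusted over the list alone (camera adjusted p = 0.0199; adjusted p = 0.709 with an estimated correlation), including FDFT1 (−1.69 ± 0.27) and SC5D. This list's adjusted p was 0.140 without hESC replicate 1 and 0.0733 without hDE replicate 1. Of 17 stress and dissociation genes 8 rose, 8 when adjusted over the list alone (camera adjusted p = 0.000654; adjusted p = 0.346 with an estimated correlation). DDIT3, a stress transcription factor, was at 216 and 385 CPM in the hDE libraries against 9.95 ± 1.23 in hESC, and JUN, an immediate-early factor, at 126 and 544 against 16.8 ± 3.88.

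The other 15 lists did not pass as lists (adjusted p from 0.0515 to 0.971). Of 12 mesoderm and mesenchyme genes 4 were lower (adjusted p = 0.0515; 0.0291 without hESC replicate 1, 0.0458 without hESC replicate 3 and 0.0453 without hDE replicate 2), and of 12 WNT targets 6 were higher (adjusted p = 0.0584; 0.0377 without hESC replicate 1, 0.0294 without hDE replicate 1, 0.0437 without hAFE replicate 1 and 0.0474 without hAFE replicate 2). Among BMP targets 5 of 12 fell, including ID1 (−4.59 ± 0.39), and 2 rose, SMAD6 and SMAD7. Higher and lower members were 4 and 3 of 18 pharyngeal genes, 6 and 4 of 15 epithelial genes, 3 and 1 of 5 posterior endoderm and liver genes, 2 and 3 of 12 neural ectoderm genes, 2 and 1 of 9 neural crest and surface ectoderm genes, and 2 and 2 of 7 amnion and trophoblast genes. They were 0 and 2 of 5 endothelium and blood genes, 2 and 3 of 13 FGF and ERK targets, 2 and 3 of 10 retinoic acid targets and 1 and 2 of 7 hedgehog targets. None of 7 measured 3-prime HOX genes (0 at an unadjusted p under 0.05, 0 in DESeq2) or of 13 mitochondrially encoded genes (2 at an unadjusted p under 0.05, 1 higher and 1 lower, 0 in DESeq2) passed in edgeR. KRT8, an epithelial keratin, rose from 48.3 ± 6.58 to 951 ± 418 CPM, with 1247 and 655 in the hDE libraries, and CDH2, N-cadherin, from 53.2 ± 3.01 to 1063 ± 10.0 CPM. CYP26A1, which degrades retinoic acid, rose from 20.9 ± 19.5 to 1638 ± 210 CPM (6.29 ± 0.78; 7.35 without hESC replicate 3).

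**Figure D1:**
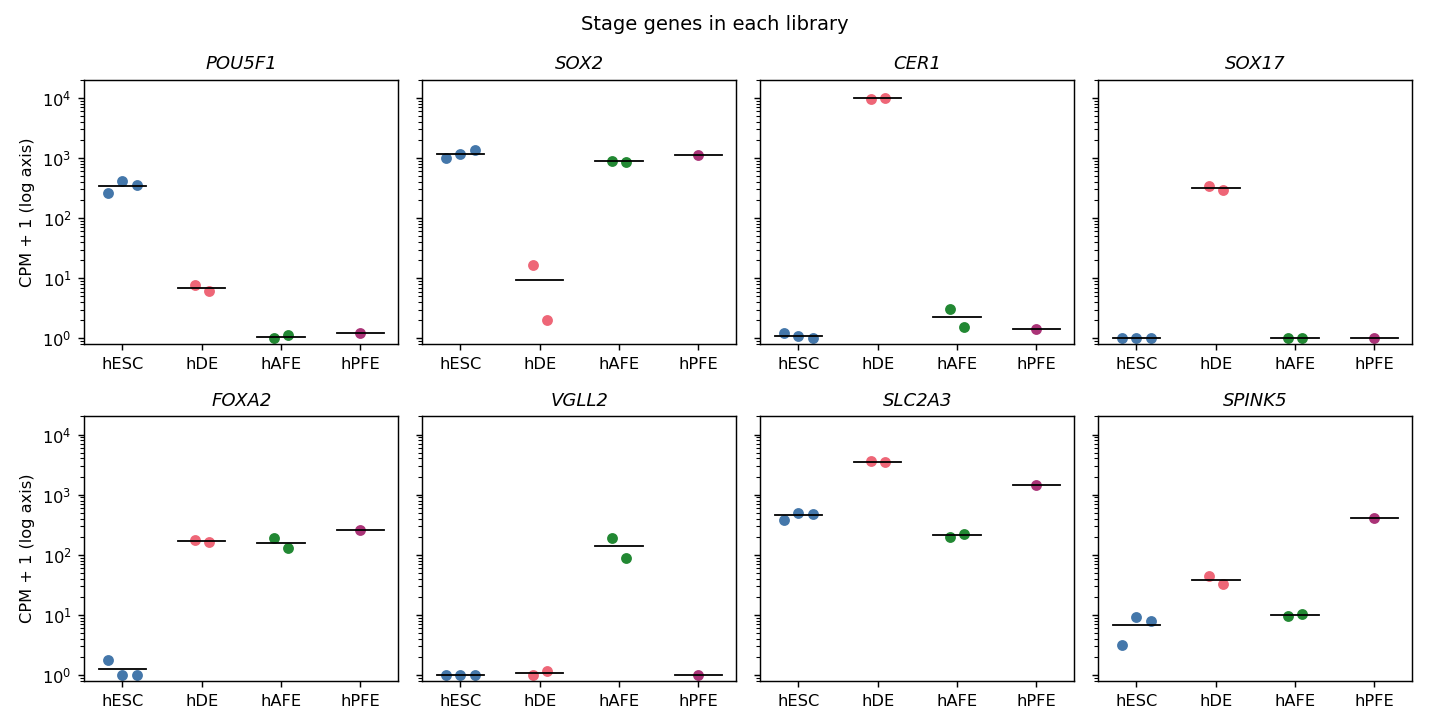
Level of 8 named genes in each of the 8 libraries (points, TMM-scaled CPM plus 1 on a log axis), with a short bar at the mean of each stage (hESC, hDE, hAFE and hPFE). CER1 stood at a mean of 9760 CPM in hDE, VGLL2 had 0 UMIs in hPFE, and SPINK5 was at 401 CPM in hPFE.

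The step from hDE to hAFE addresses how endoderm takes on an anterior foregut character. SOX2, which marks foregut endoderm as well as pluripotent cells, rose from 8.30 ± 10.3 (SD, n = 2) to 874 ± 2.65 CPM (n = 2; log2 fold change 6.75 ± 0.74 SE, adjusted p = 8.3e-05; 9.67 without hDE replicate 1 and 5.81 without hDE replicate 2). VGLL2, a transcriptional cofactor of the pharyngeal arches, was at 192 and 87.0 CPM in the hAFE libraries and had 1 UMI in hDE (ratio 1220, 219 to 48200). CER1 fell from 9760 ± 157 to 1.30 ± 1.04 CPM (−13.24 ± 0.52, adjusted p = 2.04e-07; −12.21 without hAFE replicate 2 and −14.02 without hAFE replicate 1), and SOX17 had 0 UMIs in hAFE, at least 998-fold lower. FOXA2 was at 158 ± 40.7 CPM, and its log2 fold change was −0.11 ± 0.37 (adjusted p = 0.859). In all, 3678 genes changed, 1781 higher and 1897 lower (48.4% higher), and 4629 passed the adjusted p alone. With library totals as the only scaling 60.8% of 3943 changed genes were higher, and the median of all genes moved by 0.21 on the log2 scale.

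HPGD, a prostaglandin-degrading enzyme, was at 283.9 and 39.2 CPM in the hAFE libraries and had 0 UMIs in hDE, at least 365-fold higher (139 without hAFE replicate 1 and 1010 without hAFE replicate 2). The orphan nuclear receptor genes NR2F2 and NR2F1 had ratios of 1580 (539 to 7650) and 540 (96.4 to 21400), NR2F1 at 99.8 and 33.3 CPM in the hAFE libraries. SULF1, an extracellular sulfatase, was at 376 ± 0.765 CPM (ratio 2010, 555 to 16600), and SLITRK6, a neurite-outgrowth membrane protein, at 297 and 109 CPM (ratio 560, 191 to 2720). The secreted WNT enhancer gene RSPO3, at 182 and 87.7 CPM, had a ratio of 598 (165 to 4950). The basement membrane gene NID2, at 99.8 and 19.9 CPM, had one of 434 (77.4 to 17200), and CAPN6, at 85.6 and 24.6 CPM, was at least 144-fold higher (87.7 without hAFE replicate 1 and 304 without hAFE replicate 2). MIR205HG, host of an epithelial microRNA, was at 136 and 273 CPM against 0.753 ± 0.0773 (8.06 ± 0.63; 7.46 without hAFE replicate 2). LEFTY2 and EOMES had 0 UMIs in hAFE, at least 7280-fold and 1300-fold lower, as had the noncoding RNA LINC00458, at least 1950-fold, SLC5A9, a sugar transporter, at least 797-fold (510 without hDE replicate 2), and KLKB1, a plasma protease, at least 232-fold. HPGD lies on chromosome 4 from 174490177 to 174523154 and VGLL2 on chromosome 6 from 117265558 to 117273565.

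Of 18 pharyngeal endoderm genes 13 rose and 1 fell, 15 and 1 when adjusted over the list alone (camera adjusted p = 1.58e-07; adjusted p = 0.172 with an estimated correlation). FOXE1, a thyroid and palate factor, was at 62.7 and 36.7 CPM (ratio 464, 82.8 to 18400), ISL1 at 35.4 ± 4.61 CPM (ratio 181, 49.6 to 1500), SOX3 at 50.8 ± 0.754 against 1.14 CPM (5.47 ± 0.36) and EYA1 at 58.1 ± 6.01 against 4.92 ± 1.03 CPM. TBX1, a pharyngeal arch factor, was at 4.48 and 17.4 CPM. PAX9 was at 0.407 and 32.3 CPM, and its adjusted p was 0.0825. Of 15 anterior foregut genes 5 rose and 4 fell, 7 and 4 when adjusted over the list alone (camera adjusted p = 0.386), with FOXA1 higher (2.54 ± 0.46) and HHEX lower (−5.17 ± 0.54; −6.68 without hAFE replicate 2). SHH, a foregut signal, was at 53.4 and 7.40 CPM in the hAFE libraries against 7.65 ± 4.89 in hDE (adjusted p = 0.0803).

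Of 21 definitive endoderm genes 16 fell and 1 rose, 16 and 1 when adjusted over the list alone (camera adjusted p = 3.54e-11; adjusted p = 0.0540 with an estimated correlation). GATA6 fell to 0.702 ± 0.417 CPM (−9.09 ± 0.39; −10.08 without hAFE replicate 2), and CXCR4 stood at 74.1 and 25.1 CPM in hAFE (−3.64 ± 0.43; −4.57 without hAFE replicate 1 and −3.01 without hAFE replicate 2). All 11 primitive streak genes fell, 11 when adjusted over the list alone (camera adjusted p = 2.09e-10; adjusted p = 0.177 with an estimated correlation). So did 11 of 12 NODAL and activin targets, 11 when adjusted over the list alone (camera adjusted p = 2.09e-10; adjusted p = 0.265 with an estimated correlation), a list with 10 genes that are also in another list. TDGF1, the NODAL co-receptor, fell from 975 ± 197 to 0.957 ± 0.951 CPM (−10.49 ± 0.52; −9.21 without hAFE replicate 2 and −11.65 without hAFE replicate 1). Of 21 pluripotency genes 15 fell and 1, SOX2, rose, 15 and 1 when adjusted over the list alone (camera adjusted p = 7.65e-07; adjusted p = 0.172 with an estimated correlation). NANOG had 0 UMIs in hAFE, at least 28.4-fold lower, and DPPA4, a chromatin factor of pluripotent cells, fell from 248 ± 69.5 to 19.3 ± 0.845 CPM.

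Lists of BMP, hedgehog and retinoic acid targets were higher in hAFE. Of 12 BMP targets 8 rose and 1 fell, 8 and 2 when adjusted over the list alone (camera adjusted p = 0.00194; adjusted p = 0.177 with an estimated correlation), with ID1 from 2.48 ± 0.784 to 116 ± 45.2 CPM (5.57 ± 0.41) and ID3 from 30.2 ± 12.4 to 316 ± 32.6 CPM. Of 7 hedgehog targets 4 rose and 1 fell, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.0199; adjusted p = 0.265 with an estimated correlation), with the receptor gene PTCH1 from 21.4 ± 1.65 to 99.9 ± 33.9 CPM and CCND1, cyclin D1, from 29.9 ± 0.904 to 453 ± 36.7 CPM. Of 10 retinoic acid targets 4 rose and 1 fell, 8 and 1 when adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.265 with an estimated correlation). CYP26C1 was at 65.6 and 23.1 CPM in hAFE (ratio 364, 64.8 to 14400), while CYP26A1 was at 154 and 30.3 CPM against 1638 ± 210 in hDE (−4.19 ± 0.84; −5.75 without hAFE replicate 1 and −3.40 without hAFE replicate 2). Of 7 amnion and trophoblast genes 5 rose, 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00197; adjusted p = 0.177 with an estimated correlation). BMP4, which many tissues use, was at 523 and 279.5 CPM in hAFE against 14.3 and 50.5 in hDE, and GATA3 rose from 8.70 ± 1.69 to 33.6 ± 7.12 CPM.

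Of 18 G2 and M genes 9 rose, 9 when adjusted over the list alone (camera adjusted p = 2.65e-07; adjusted p = 0.265 with an estimated correlation), with TOP2A at 1062 ± 88.4 CPM (1.75 ± 0.21). Of 17 S phase genes 6 rose, 6 when adjusted over the list alone (camera adjusted p = 0.000516; adjusted p = 0.517 with an estimated correlation). Of 19 glycolysis genes 7 fell, 7 when adjusted over the list alone (camera adjusted p = 0.00399; adjusted p = 0.570 with an estimated correlation), with SLC2A3 at 211 ± 19.9 CPM (−4.06 ± 0.25) and ENO1, enolase, at 661 ± 128 against 1888 ± 449 CPM. Of 17 stress and dissociation genes 8 fell, 9 when adjusted over the list alone (camera adjusted p = 0.00399; adjusted p = 0.398 with an estimated correlation). ATF3 fell from 136 and 308 CPM in the hDE libraries to 11.1 ± 5.29 CPM (−4.23 ± 0.43; −4.92 without hAFE replicate 2 and −3.53 without hDE replicate 2). The other 12 lists, anterior foregut among them, had adjusted p from 0.0606 to 0.971. Without 1 library 3 of them passed. The 3-prime HOX genes had an adjusted p of 0.0163 without hAFE replicate 1 and 0.0458 without hESC replicate 1, and posterior endoderm and liver genes 0.0171 without hDE replicate 1. Mitochondrially encoded genes had 0.0469 without hESC replicate 1, 0.00427 without hDE replicate 2 and 0.0231 without hAFE replicate 2. Of 15 epithelial genes 4 rose and 3 fell, among them KRT8, which fell to 183 ± 23.9 CPM, and GRHL2, an epithelial transcription factor, which rose from 2.89 to 98.4 ± 25.7 CPM.

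**Figure D2:**
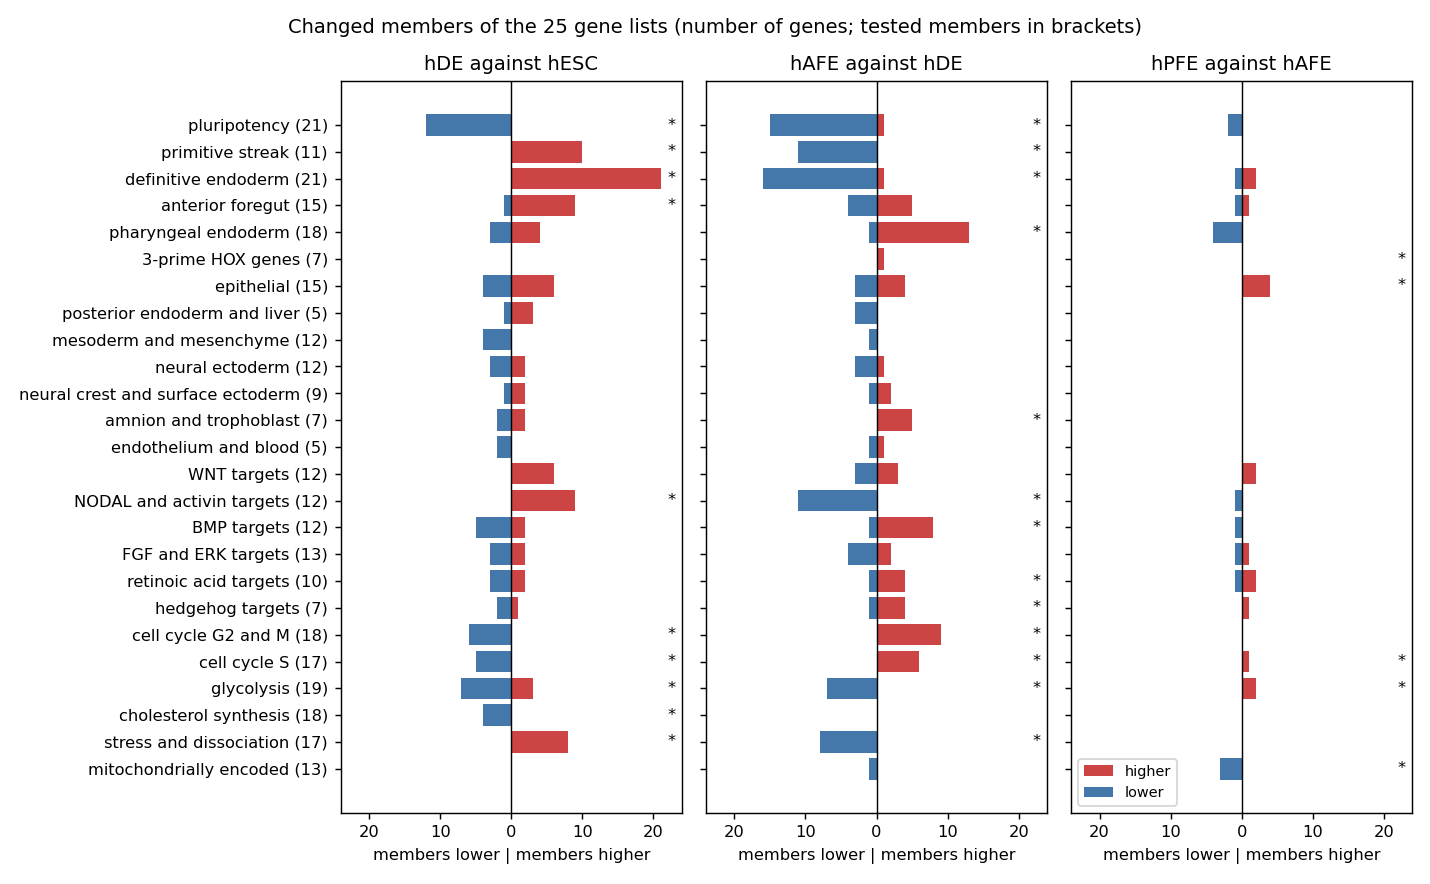
Number of measured members of each of the 25 gene lists that rose (right) or fell (left) in each of the 3 comparisons, with an asterisk where the camera adjusted p is under 0.05. All 21 definitive endoderm genes rose in hDE against hESC, and 13 of 18 pharyngeal endoderm genes rose in hAFE against hDE.

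The step from hAFE to hPFE addresses how anterior foregut becomes pharyngeal, and rests on 1 hPFE library with no replicate check. SPINK5, an epithelial protease inhibitor, was at 401 CPM in hPFE (Poisson interval 383 to 420) against 8.98 ± 0.596 in hAFE (SD, n = 2; log2 fold change 5.46 ± 0.51 SE, adjusted p = 0.00131). CDH11, a mesenchymal cadherin, was at 446 CPM (427 to 465) against 8.56 and 40.3 in the hAFE libraries (4.09 ± 0.57, adjusted p = 0.0063; 5.70 without hAFE replicate 2 and 3.47 without hAFE replicate 1). VGLL2 had 0 UMIs in hPFE, at least 176-fold lower (297 without hAFE replicate 2), and SOX3 fell from 50.8 ± 0.754 to 5.61 CPM (3.67 to 8.22; adjusted p = 0.0039). In all, 659 genes changed, 327 higher and 332 lower (49.6% higher), and 664 passed the adjusted p alone. The count was 342 without hAFE replicate 2, of which 245 are among the 659. The share of higher calls was 73.1% with library totals as the only scaling, which moved the median of all genes by 0.19 on the log2 scale, 38.4% in DESeq2, 38.5% with no filter on low counts, 59.9% with all deposited barcodes and 32.9% without hAFE replicate 1.

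The largest rises included SPINK1, a protease inhibitor, at 54.8 CPM (48.3 to 62.0) against 1 UMI in hAFE (ratio 520, 92.4 to 20600), and PCDH8, a protocadherin, at 90.5 CPM (82.0 to 99.5) against 0.845 ± 0.618 (6.45 ± 0.81; 7.73 without hAFE replicate 2). GPC4, a heparan sulfate proteoglycan, was at 92.0 CPM (83.4 to 101) against 9.50 ± 1.55 (3.31 ± 0.32), and DPP10 at 63.5 CPM against 4.65 ± 3.69 (3.59 ± 0.50; 4.95 without hAFE replicate 2). NEFM, a neurofilament gene, was at 93.9 CPM against 2.85 and 14.1. LRAT, which stores retinol as esters, stood at 64.1 against 2.38 CPM, but its call was lost without either hAFE library. HPGD fell from 283.9 and 39.2 CPM in the hAFE libraries to 2.38 CPM (−6.06 ± 1.19; −4.04 without hAFE replicate 1 and −6.89 without hAFE replicate 2), and SLITRK6 from 297 and 109 to 5.83 CPM (−5.11 ± 0.66; −4.22 without hAFE replicate 1). PTN, a growth factor gene, was at 266 and 556 CPM in hAFE against 44.0 in hPFE (−3.23 ± 0.58; −2.60 without hAFE replicate 2). SPINK5 lies on chromosome 5 from 148025683 to 148137289.

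Of 15 epithelial genes 4 rose, 7 when adjusted over the list alone (camera adjusted p = 0.000101; adjusted p = 0.172 with an estimated correlation). KRT8 rose from 183 ± 23.9 to 769 CPM (744 to 795; 2.07 ± 0.34, adjusted p = 0.0127). KRT19 stood at 830.3 against 328 ± 33.1 CPM (adjusted p = 0.0235; 0.0701 without hAFE replicate 2) and KRT18 at 1199 against 482 ± 91.9 (adjusted p = 0.0409; 0.127 without hAFE replicate 2). Of 19 glycolysis genes 2 rose, 6 when adjusted over the list alone (camera adjusted p = 6.54e-05; adjusted p = 0.384 with an estimated correlation), with SLC2A3 at 1452 CPM (1420 to 1490) against 211 ± 19.9. None of 7 measured 3-prime HOX genes, which pattern the hindbrain and pharyngeal region, passed in edgeR (3 higher at an unadjusted p under 0.05, 0 in DESeq2), although the list as a whole was higher (camera adjusted p = 0.000334; adjusted p = 0.420 with an estimated correlation). HOXB3 stood at 24.2 CPM (19.9 to 29.1) against 1.97 ± 1.64 (adjusted p = 0.113), and HOXC4 was at least 8.87-fold higher than its 0 UMIs in hAFE. Of 17 S phase genes 1, MCM5, rose, 3 when adjusted over the list alone (camera adjusted p = 0.00908; adjusted p = 0.588 with an estimated correlation). A replicate block ended the call of this list. Without hAFE replicate 2 the adjusted p of MCM5 was 0.0871 and that of the list 0.0573. GATA6 was higher in hPFE, at 24 CPM (19.7 to 28.9) against 0.702 ± 0.417 (4.82 ± 0.45; 5.81 without hAFE replicate 2).

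Ribosomal protein genes, a group chosen after the data were seen, were low in hPFE. Of 84 tested, 52 fell and 0 rose (median log2 fold change −1.67, and −1.43 with library totals only), and they made up 2.77% of UMIs in hPFE against 6.01 and 8.74% in the hAFE libraries and 6.96 to 9.45% in the other 5. Of the 304 genes that fell in hPFE and have a transcript length, 74 have a longest coding transcript under 1000 nt (24.3%), against 0 of 313 that rose and 475 of 13720 tested (3.46%). In the same library, of 13 mitochondrially encoded genes 3 fell, 6 when adjusted over the list alone (camera adjusted p = 5.1e-06; adjusted p = 0.429 with an estimated correlation). MT-ND5, a subunit of respiratory complex I, fell from 912 ± 42.4 to 205.5 CPM (−2.15 ± 0.31) and MT-ND4L, another, from 144 ± 60.7 to 23.1 CPM. MT-CO1, given after its values were seen, was at 1172 CPM in hPFE against 711.7 and 1009 in the hAFE libraries (adjusted p = 0.515).

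**Figure D3:**
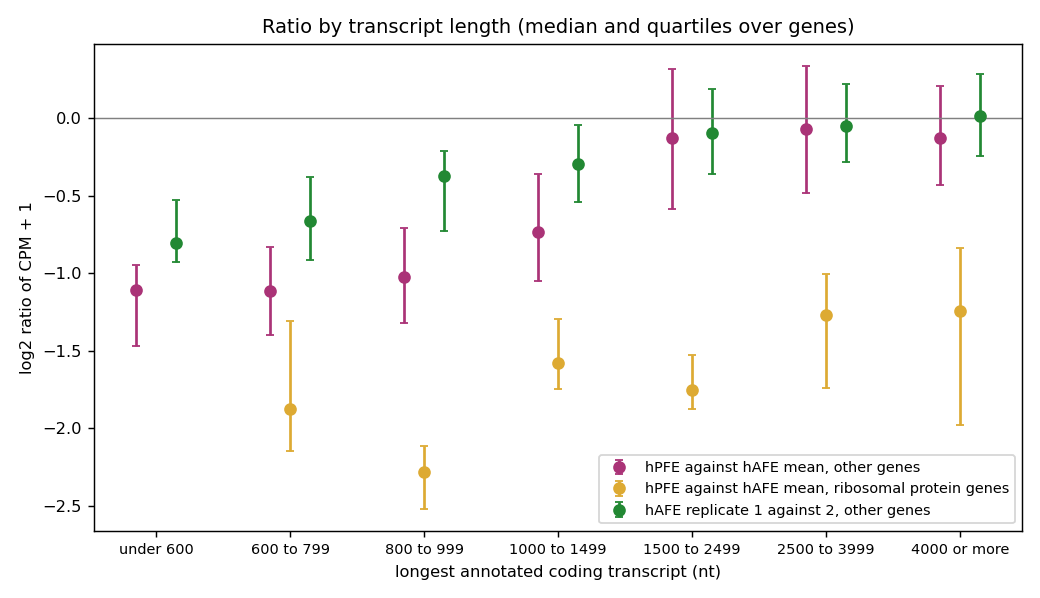
Median and quartiles of the log2 ratio of CPM plus 1 by length of the longest coding transcript, for hPFE over the hAFE mean (ribosomal protein genes and other genes apart) and for hAFE replicate 1 over replicate 2. In hPFE over hAFE the median of other genes under 1000 nt was −1.08 and that of genes of 1500 nt or more −0.12, and the bins of ribosomal protein genes hold 6 to 21 genes.

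Of 18 pharyngeal endoderm genes 4 fell in hPFE and none rose, 1 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.0606; 0.00411 without hAFE replicate 1). TBX3 fell from 49.7 ± 7.47 to 2.38 CPM (−4.37 ± 0.67). PAX9 was at 30.9 CPM (26.0 to 36.4) in hPFE against 0.407 and 32.3 in hAFE (adjusted p = 0.688), and TBX1 at 2.38 against 4.48 and 17.4. SOX2 at 1127 CPM (1100 to 1160; adjusted p = 0.793) and FOXA2 at 253 CPM (239 to 268; adjusted p = 0.396) did not pass. Of 10 retinoic acid targets 2 rose and 1 fell, 3 and 2 when adjusted over the list alone, with TGM2, a transglutaminase, at 17.7 CPM (at least 55.9-fold higher) and CYP26C1 at 0 UMIs (at least 52.6-fold lower, and 101 without hAFE replicate 2). Of 21 pluripotency genes 2 fell, DPPA4 (−3.89 ± 0.50) and the RNA-binding gene LIN28A (−1.44 ± 0.28). The 20 lists that were not called had adjusted p from 0.0606 to 0.971. BMP targets among them (adjusted p = 0.0999) had 0.0371 without hAFE replicate 1.

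The share of cells with a UMI of a stage marker was taken after thinning each cell to 800 UMIs. Median depths before thinning were 1357.5, 963 and 950 UMIs in hESC, 924 and 1323 in hDE, 2853 and 1697 in hAFE and 1365 in hPFE, and 53 to 1316 shallower cells per library were left out. CER1 had a UMI in 97.5 and 99.4% of hDE cells and in 0, 0.036 and 0% of hESC cells, the stage that should lack it (unthinned 99.4 and 99.8% against 0.086, 0.025 and 0%). SOX17 had one in 20.3 and 16.3% of hDE cells (unthinned 35.9 and 35.3%) and in 0% of hESC cells, which allows up to 0.164, 0.107 and 0.096%. FOXA2 was seen in 12.1 and 10.5% of hDE, 16.4 and 11.2% of hAFE and 20.9% of hPFE cells (18.5 to 23.5%), against 0.109, 0 and 0% in hESC (unthinned 24 and 24.6%, 40.6 and 26.0%, and 42.4%, against 0.172, 0 and 0%). POU5F1 was seen in 19, 28.8 and 24.4% of hESC cells and in 0% of hAFE and hPFE cells (unthinned 41.0, 41.5 and 33.8%, against 0, 0.045 and 0.074%). SOX2 was seen in 49.3, 53.9 and 59.8% of hESC, 0.146 and 0.063% of hDE, 44.7 and 45.7% of hAFE and 64.7% of hPFE cells (unthinned 69.7, 64.3 and 68.9%, 1.87 and 0.251%, 72.9 and 68.5%, and 80.7%). PAX9 was seen in 0 and 2.34% of hAFE cells and 2.63% of hPFE cells (unthinned 0.198, 8.27 and 8.33%), and SHH in 6.20, 0.742 and 4.28% (unthinned 16.2, 2.14 and 12.5%). NKX2-1, a thyroid and lung factor, and PECAM1, an endothelial marker, had no UMI in any thinned cell. An exact two-sided permutation test cannot go below p = 0.1 with 3 against 2 libraries or 0.33 with 2 against 2, so shares were not tested. The labels call the cells sorted and name no gate, which the shares would reflect. The shares count cells in which a UMI was seen and rise with depth, as the unthinned values of SOX17 and FOXA2 show. They are therefore not the fractions of cells that express a marker. Barcodes left out for too few genes held CER1 at 9136 CPM in hDE replicate 1 and 9310 CPM in hDE replicate 2. Such barcodes mix free RNA and shallow cells, so the shares cannot tell a cell's own CER1 UMIs from free RNA.

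**Figure D4:**
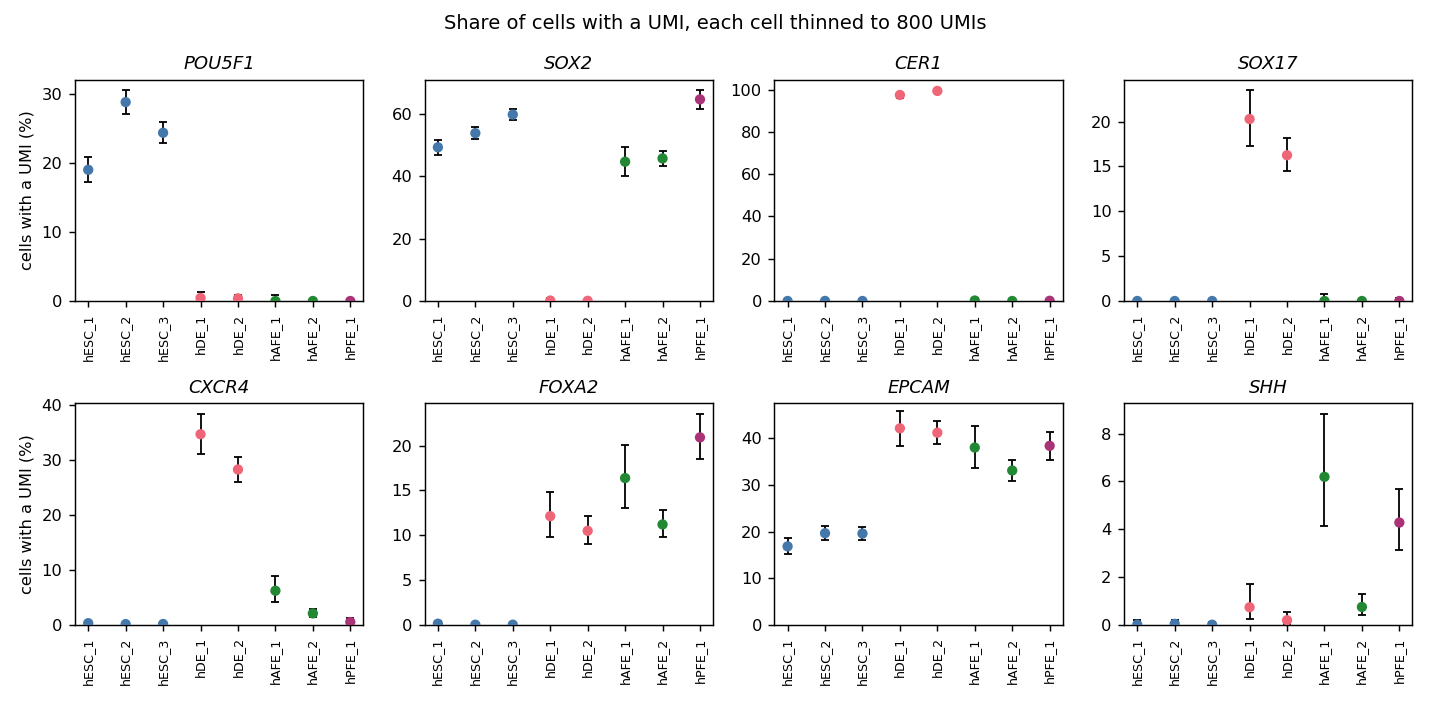
Percent of cells with a UMI of 8 stage markers in each library after thinning to 800 UMIs per cell (points), with exact 95% binomial intervals (bars). CER1 was seen in 97.5 and 99.4% of hDE cells and in at most 0.221% of cells of any other library.

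Clustering gave 9 clusters, and 99.75% of cells lay in a cluster made up mostly of their own stage. Clusters 1 and 5 were pluripotent-like, clusters 2 and 8 definitive endoderm-like, clusters 3 and 4 foregut-like and cluster 9 neural-like. Cluster 7 (681 cells, 1 raised marker) stayed unnamed, as did cluster 6, which raised 7 foregut markers but held SIX3, a neural marker, and no foregut marker among its 10 leading genes. Clusters 3 and 4 raised fewer foregut markers, 5 and 4, and their 10 leading genes held no foregut marker either, nor a marker of another type. The missing name of cluster 6 therefore does not show that it lacked a foregut identity. The leading genes of cluster 5 held 1 pluripotent and 1 endothelial or blood marker. Cluster 9 raised 6 neural markers, but also 3 of mesoderm and mesenchyme and 3 of neural crest or surface ectoderm. Cluster 1 was led by ESRG and POU5F1, cluster 2 by S100A14, PRSS2 and TTN, cluster 3 by DLK1, PRTG and VGLL2, and cluster 4 by CDH11, SPINK5 and SEMA3D. Replicates of a stage were spread unevenly. Cluster 7 held 25.1% of hESC replicate 1 against 1.71 and 0.585% of the other hESC libraries, and cluster 6 held 64.8% of hAFE replicate 1 against 17.1% of replicate 2. With only cells of at least 3000 UMIs, 1 cluster held 97.2% of hAFE replicate 1 and 1.96% of replicate 2, and another 96.4% of hDE replicate 1 and 0.995% of replicate 2. Cluster 4 held 97.8% of hPFE cells, and since hPFE is 1 library it cannot be told from that library. Clusters 5, 6 and 8, led by SFRP2, SLITRK6 and CER1, held deep barcodes, with median UMIs of 14155, 6028 and 16157, so clusters of a stage differ in depth. They differ in mitochondrial share as well. Its median was 0.089% in cluster 7 against 0.45 and 1.292% in clusters 1 and 5, and 0.198% in cluster 3 against 0.956% in cluster 6. With at least 3000 UMIs, 1 cluster with a median of 1.137% held 52.6% of hAFE replicate 2, and another with 0.169% held 45.3%. Whether the uneven spread of replicates follows these differences was not tested.

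At hDE 1111 genes peaked and 858 dipped between hESC and hAFE, against 250.7 and 257.9 for independent lists and a mean of 0.1 over 20 simulated sets of unchanged libraries. SLC2A3 went from 451 through 3519 to 211 CPM, and KRT8 from 48.3 through 951 to 183 CPM. SOX2 dipped from 1181 through 8.30 to 874 CPM, and ID1 dipped as well, from 59.4 through 2.48 to 116 CPM. At hAFE 57 genes peaked and 104 dipped between hDE and hPFE, against 35.4 and 37.1 for independent lists and a simulated mean of 0.05. VGLL2 and SOX3 peaked there, and SLC2A3, KRT8 and GATA6 dipped. The successive comparisons share the libraries of the middle stage, so part of the excess over independent lists may come from them. The simulated sets held no changed genes, so their means count false calls only and cannot gauge that part.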

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

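The tests of all 3 patterns weighed here were chosen after the results were seen. Barcodes with fewer than 500 genes, which the reported comparisons leave out, carried stage genes above the level of the preceding stage. CER1 was at 9136 CPM in such barcodes of hDE replicate 1 and 9310 CPM in those of hDE replicate 2, against 3.16, 0 and 0 in the hESC libraries. SPINK5 was at 479.6 CPM in hPFE against 5.75 and 11.3 in hAFE. VGLL2 was at 167 CPM in hAFE replicate 1 and 105 CPM in hAFE replicate 2, against 0 in both hDE libraries.

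Ribosomal protein genes and other short transcripts were low in hPFE against hAFE. A fall of the ribosomal protein genes alone is argued against, since 176 other genes under 1000 nt had a median log2 ratio of −1.082. For these other genes the values are those that a loss of short transcripts needs, with short minus long genes at −0.963 (95% interval −1.01 to −0.884, 2000 resamples). Length is argued against as the whole account of the ribosomal protein genes under 1000 nt, since they lay a further −0.866 below the other short genes (−1.303 to −0.618). Both intervals resample genes and hold no spread between libraries. Ribosomal protein genes of 1500 nt or more had medians of −1.751, −1.266 and −1.243 in length bins of 16, 6 and 8 genes, against −0.124, −0.067 and −0.129 for other genes. Lengths are those of the longest annotated coding transcript, which need not be the one expressed, so these longer bins cannot decide. A difference between the stages cannot be told apart from a feature of the hPFE library, since hPFE has 1 library and the same measure between the hAFE replicates, replicate 1 over replicate 2, was already −0.533.

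The hAFE replicates differed, with 194 of 4421 genes at least 2-fold apart (hDE 119), 38 of the 183 with a length being under 1000 nt. These 4421 genes had a mean of at least 50 CPM over all 8 libraries, and some can be lower in hAFE. Among genes picked after their values were seen, PAX9 had 1 and 227 UMIs (0.407 and 32.3 CPM), SIX3 733 and 285 (298.6 and 40.6 CPM), SHH 131 and 52 (53.4 and 7.40 CPM), PAX1 0 and 214 (0 and 30.5 CPM) and HESX1 268 and 46 (109 and 6.55 CPM). Replicate 1 is the shallower library, so the UMIs alone do not give the size of these gaps. Leftover hDE cells are excluded by CER1, at 0.0209% of its hDE level in replicate 1 and 0.0058% in replicate 2. Over 257 genes of at least 1500 nt, the replicate 2 library was not placed further along from hDE to hPFE than replicate 1. Its position differed by −0.046 (−0.079 to −0.013). This interval resamples genes and holds no spread between libraries, and hPFE is 1 library. Of the 194 genes apart, however, 68 of the 126 of at least 1500 nt, and 2 of the 38 under 1000 nt, were nearer hPFE in replicate 2. A shift limited to some genes and a difference in position along the gut both stay open and untested, since PAX9, PAX1 and SIX3 were nearer hPFE in replicate 2 while SHH and TBX1 were not.

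Among barcodes with at least 3000 UMIs, 912 of 3259 had under 0.4% mitochondrial UMIs, with 173 of all 3259 within 0.1 percentage points of that limit, 293 of 662 in hAFE replicate 2 but 16 of 248 in hAFE replicate 1. In the 5 libraries with at least 50 low barcodes (852 in all) nuclei are argued against, since the nuclear RNA MALAT1 was lower in the low barcodes of each (median log2 ratio −0.918, every 95% interval below 0), while in the other 3 (60 barcodes, median −0.112) every interval reached 0 and nuclei stay open. Free RNA stays open, since MALAT1 in the low barcodes set against barcodes under 500 genes (median log2 ratio −0.844) ran from −1.42 to 0.02 over the libraries, and barcodes under 500 genes mix free RNA and shallow cells. Cytoplasm without nucleus and mitochondria stays open too, since KCNQ1OT1, another nuclear RNA with few UMIs, was higher in the low barcodes of 3 of those 5 libraries (median log2 ratio over the 5 of 0.279), with its interval below 0 in 1 and above 0 in 0. NEAT1, also a nuclear RNA with few UMIs, went the other way. It was lower in the low barcodes of all 5 (log2 ratios from −2.054 to −0.181), with its interval below 0 in 2. The intervals of these 3 RNAs resample barcodes within each library. No biological explanation was tested.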

How the results depend on the processing

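The alternatives chosen only after the data were seen are cells with at least 3000 UMIs, ribosomal protein and mitochondrial genes left out, and genes of at least 1500 nt. Of 49 alternative counts of changed genes 45 were within 1.5 times the value reported, and every gene called in both the reported and an alternative setting kept its direction. The exceptions all concern hPFE against hAFE (659 reported), with 1067 in DESeq2, 1630 with no filter on low counts and 1059 with only the 2 stages in the model. The cause was not tested, except that dropping the filter tests more genes (28546). Leaving out an hAFE replicate gave 342 to 851 genes, where the remaining hAFE library is assumed to vary like the other stages. For hDE against hESC leaving out 1 library gave 3801 to 4441 genes, and for hAFE against hDE 2950 to 3257.

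With the estimated inter-gene correlation 1 list call remained of 28, and this alternative differs from the reported test only in that correlation. fry, which tests whether a list's genes move on balance and not against other genes, gave 28 calls, 20 of them shared. In hPFE against hAFE only the epithelial list kept its call under fry. The 3-prime HOX, S phase, glycolysis and mitochondrially encoded lists lost theirs there. Also lost were glycolysis and cholesterol synthesis in hDE, and S phase and stress and dissociation in hAFE. Of 750 list tests 683 kept their side of the threshold, 26 passed newly and 41 were lost. Median signs of lists not called turned under another scaling for pluripotency in hPFE, epithelial and mesoderm genes in hAFE and BMP targets in hDE. Of the named genes called, 96 of 105 in hDE, 88 of 98 in hAFE and 30 of 48 in hPFE kept their call in every setting that tested them. Some settings left a gene untested. Clusters numbered 15 at resolution 1.0 and 14 with at least 3000 UMIs, against 9. Of 640 shares 158 moved beyond their spread, 80 of them without thinning. Thinning every library to the smallest total gave 3528, 3030 and 653 changed genes in the 3 comparisons, against 4633, 3678 and 659.

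Nothing in the labels says whether libraries with the same replicate number belong together, and the reported model does not pair them. Where a stage has 2 libraries their deviations mirror each other, so the correlations below cannot settle pairing. Deviations of same-numbered libraries correlated across genes at 0.165, 0.030 and 0.115 for replicate 1 (hESC with hDE, hESC with hAFE, hDE with hAFE), and at 0.079 and 0.069 for replicate 2 of hESC with hDE and hAFE. A replicate block gave 4395, 3733 and 837 changed genes in the 3 comparisons, and 29 list calls, 26 of them shared.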

Other observations

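No test in this part was planned, and the genes named here were chosen after their values were seen. A small group of neural-like cells stood apart, nearly all of them in 1 stem cell library. Cluster 9 held 43 cells, 39 of them from hESC replicate 1, 3 from hDE replicate 1 and 1 from hDE replicate 2, and none from the other hESC libraries. Its defining genes included POU3F2, a neural progenitor factor, at 1012 CPM against 3.3 in the deep pluripotent-like cells of hESC replicate 1, DCX, a microtubule protein of young neurons, at 339 against 5.0, STMN2 at 380 against 5.8, FABP7, a radial glia gene, at 682 against 40.8, and EN2, a midbrain and hindbrain factor, at 211 against 0.3. TFAP2B, a neural crest factor, was at 357 CPM against 0. In the same cells POU5F1 was at 22.9 CPM against 224 and L1TD1, an RNA-binding protein of pluripotent cells, at 252 against 3386, while SOX2 was at 1067 against 983. These are sums over all cells of the cluster, with no replicate and no test.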
